A study of Acetivibrio thermocellus DSM 1313 with 15 samples.

How the data were processed

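RNA was taken from cultures in defined medium at mid-log phase, at an OD600 of 0.45 to 0.50, per the labels' protocols. RNA was purified on columns and treated with DNase, and libraries and sequencing were done by a commercial service. The deposited values are raw read counts per gene, 1 column per library. BWA and SAMtools are named in the submitters' processing notes. Their versions, the genome build, the annotation, the counting program and its use of strand are not given in the sources used here. The 15 columns were matched to sample titles by strain, substrate and replicate. The 3 columns of KJC335 on cellobiose carry the code CB, which no source spells out, and were matched because cellobiose was the substrate left for that strain. The series' design text spells the parent both KJC355 and KJC335, taken here as 1 strain. The replicates are called biological in the labels, and no shared culture or day is given for them. The design text of the series places the KJC335 data in an earlier submission. The parent libraries may thus have been made and sequenced apart from those of the evolved strains, and such a batch would coincide with every comparison of an evolved strain with the parent. It would not touch comparisons within KJC335, within KJCXn4 or between the evolved strains.

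Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Rows were kept by filterByExpr, which left 3005 of 3105 and removed 100. Library sizes were scaled by TMM factors, and 1 model with a term for each of the 5 groups was fitted to all 15 libraries, so that the groups share one estimate of the spread. The common dispersion was 0.00785, a biological coefficient of variation of 8.86%. Each comparison was tested with the quasi-likelihood test (glmQLFit and glmQLFTest, 2-sided), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. A second count took called genes with an absolute log2 fold change of at least 1. CPM values use the TMM-scaled library sizes, and principal components were taken from log2 CPM with a prior count of 2. On counts simulated from these libraries with 200 changed genes, between 80.8% and 86% of 1.5-fold changes and between 97% and 99.0% of 2-fold changes were recovered over the 5 comparisons, and between 2.14% and 4.69% of the calls were false. Far more genes were called in the data, so these shares do not cover comparisons in which most genes change.

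The genes to name were set by rule before the data were examined. In each comparison these were the 8 largest rises and the 8 largest falls among called genes with an absolute log2 fold change of at least 1, a mean log2 CPM of at least 4 and groups that do not overlap, which chance gives for 10% of genes with 3 libraries against 3. The rule also took XylA, XylB and other fixed genes of hydrolysis and fermentation where identified. The files do not pair tags with names, so of the fixed genes XylA and XylB are reported, and of the others at most 2 tags each way in the main results. For the same reason 28 fixed gene lists were not tested, and rRNA and tRNA rows were neither identified nor removed.

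Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 17.5 and 130.8, so each library was counted once. Same-numbered replicates of KJC19-9 and KJCXn4 on xylose deviated together from their group means (r across genes between 0.134 and 0.245 for the 3 pairs), which by the limit of 0.1 set in advance pairs them, although no label says why. In the other 4 comparisons at least 1 pair fell under that limit.

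The alternatives set before the data were examined were RLE factors, library totals without further scaling, DESeq2 1.42.0, no filter, a filter of at least 10 CPM in at least 3 libraries, a fit to the 6 libraries compared, a replicate block, and each library left out in turn. Several analyses were chosen after the data had been seen. These were the runs of consecutive rows, the comparisons with KJC335 on cellobiose, the correlations between comparisons that share no library, the genes that separate sets of groups, and the sets of near-identical rows. A gene was said to separate a set of groups where its group means of log2(CPM + 1) differed by at least 1 between the set and the rest, the highest mean exceeded 4 and every library lay on its side. A first version of that rule used the group means alone, and its count is given where it differs. The rule for near-identical rows went through 3 versions, whose counts are all given in the closing section. The version used took rows with a mean count over 1000 that differed by under 0.2 on the log2 scale in every library, in sets of at least 3, with a level that varied at least 2-fold between libraries.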

Results

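Transcript abundance was measured by RNA sequencing in cultures of Acetivibrio thermocellus (formerly Clostridium thermocellum) DSM 1313, an anaerobic, thermophilic bacterium that degrades cellulose. The parent strain, KJC335, lacks hpt and carries xylA and xylB at that locus. In bacterial xylose use, xylA commonly encodes xylose isomerase and xylB xylulokinase, which together convert xylose to xylulose 5-phosphate. KJC19-9 and KJCXn4 were obtained from KJC335 by adaptive laboratory evolution, KJC19-9 on xylose and KJCXn4 on xylose together with xylan, the xylose polymer of plant cell walls. There were 5 groups of 3 biological replicates: KJC335 on cellobiose, KJC335 on xylose, KJC19-9 on xylose, KJCXn4 on xylose, and KJCXn4 on xylose plus xylan. The count table held 3105 rows, of which 3103 carried a locus tag and the others were named XylA and XylB. Library totals ranged from 23363920 to 33400513 counts, and the 10 highest rows of a library took between 19.3% and 25.5% of its counts. The files do not pair locus tags with gene names or products, so none of the 28 gene lists fixed in advance could be tested. At most 2 tags in each direction are given per comparison in these main results, and the closing section gives further tags.

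Replicates lay close together. Pearson's r of log2 CPM (read counts scaled to a common library size) across genes, which are not independent replicates, was between 0.995 and 0.998 for pairs of replicates. The first principal component held 47.3% of the variance. KJC335 on xylose had a mean score of 27.4 ± 0.684 (SD, n = 3) and KJCXn4 on xylose one of 16.0 ± 1.19 (SD, n = 3). The scores of the other groups were negative, at -6.56 ± 2.18 for KJC335 on cellobiose, -18.4 ± 0.946 for KJC19-9 on xylose and -18.5 ± 0.626 for KJCXn4 on xylose plus xylan (SD, n = 3 each). The second component held 21.8% of the variance, and KJC335 on cellobiose had the lowest mean score on it, at -24.4 ± 1.30 (SD, n = 3).

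**Figure D1:**
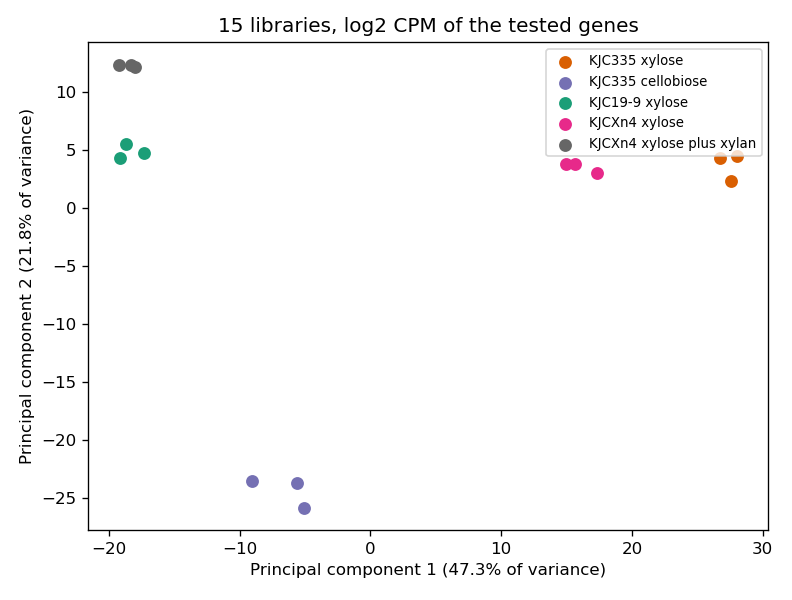
Scores of the 15 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; each point is 1 library and each colour 1 group. On the first component the xylose libraries of KJC335 and KJCXn4 have positive scores and the libraries of the other 3 groups negative ones.

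The engineered genes had high read counts in every library. XylA ranked between 68 and 152 from the top of the 3105 rows over the 15 libraries, and XylB between 51 and 119. These ranks are of read counts, without correction for gene length. In KJC335, XylA rose from 1211 ± 57.3 CPM on cellobiose to 1907 ± 160.2 CPM on xylose (SD, n = 3 each), a log2 fold change of 0.65 with a standard error of 0.071 (edgeR adjusted p = 8.01e-07). XylB rose from 1486 ± 12.4 to 2299 ± 206.7 CPM (SD, n = 3 each), a log2 fold change of 0.63 with a standard error of 0.082 (edgeR adjusted p = 5.60e-06). On xylose, XylA was at 1845 ± 98.2 CPM in KJC19-9 and at 2056 ± 122.5 CPM in KJCXn4 (SD, n = 3 each). Neither value differed from the parent by edgeR, with adjusted p = 0.558 and 0.234. XylB in KJC19-9 had a log2 fold change of -0.22 against the parent (edgeR adjusted p = 0.026), a call with adjusted p between 0.0026 and 0.079 over the alternatives that was lost without KJC335 xylose replicate 2 (adjusted p = 0.079), without KJC19-9 xylose replicate 1 (0.055) and without KJC19-9 xylose replicate 3 (0.061). XylB in KJCXn4 had one of 0.14 (edgeR adjusted p = 0.182). With xylan added, both genes fell in KJCXn4, XylA with a log2 fold change of -0.42 (edgeR adjusted p = 8.26e-05) and XylB with one of -0.31 (edgeR adjusted p = 0.0035).

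The response of the unevolved strain to the engineered sugar was read from KJC335 on xylose against KJC335 on cellobiose. CLO1313_RS14785 rose from 9.99 ± 2.18 to 362.3 ± 77.0 CPM and its neighbour in tag order, CLO1313_RS14790, from 13.6 ± 0.907 to 389.3 ± 84.6 CPM (SD, n = 3 each). Their log2 fold changes were 5.18 and 4.84, with standard errors of 0.19 and 0.15 and edgeR adjusted p of 9.75e-12 and 2.02e-12. CLO1313_RS09935 fell from 725.2 ± 426.7 to 6.11 ± 0.337 CPM and CLO1313_RS09930 from 468.4 ± 267.5 to 32.6 ± 2.39 CPM (SD, n = 3 each), with log2 fold changes of -6.89 and -3.84. The 8 largest rises named by the rule had log2 fold changes of 3.30 to 5.18, and the 8 largest falls ones of -2.94 to -6.89. The rule's floor on mean log2 CPM over all libraries left out larger rises. In 1 stretch of 5 consecutive rows the log2 fold changes had a median of 4.14 and reached 7.61, with median levels of 1.78 and 63.7 CPM. The same rows had a median of -4.24 with xylan in KJCXn4 and of 4.31 in KJCXn4 over KJC19-9 on xylose.

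Of 3005 genes tested, 1944 were called between xylose and cellobiose in KJC335, 963 higher and 981 lower on xylose (edgeR quasi-likelihood test, 2-sided, Benjamini-Hochberg adjustment). A change of at least 2-fold was found for 420 of them, 252 higher and 168 lower. Scaling by library totals alone gave 1318 higher and 664 lower, with 332 higher and 119 lower by at least 2-fold, and moved the median log2 fold change of all genes by 0.16. Many of the 2-fold changes lay side by side in the table, which lists the tags nearly in rising order. There were 17 runs of at least 5 consecutive rows called with a 2-fold change in 1 direction, 11 higher and 6 lower. They took in 126 rows, against at most 6 in 1000 shuffles of row order. A shuffle moves each row on its own, so neighbours that vary together for any reason exceed it, here and in the other comparisons. The run that ended in CLO1313_RS14790 held 8 rows, with a median log2 fold change of 3.64.

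**Figure D2:**
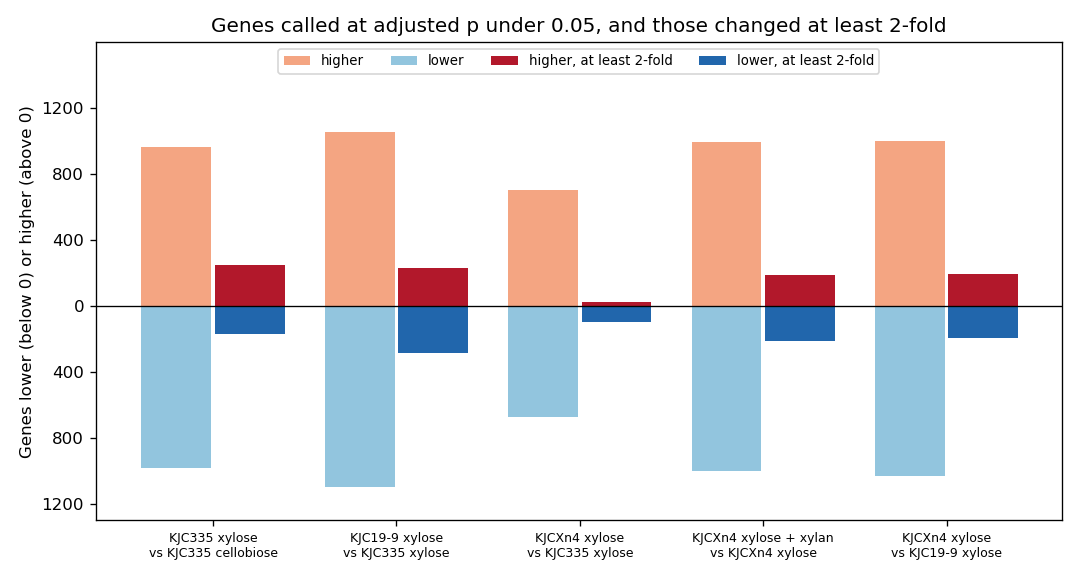
Number of genes called higher (above 0) and lower (below 0) in each of the 5 comparisons; pale bars give all genes at an adjusted p under 0.05 and dark bars those changed at least 2-fold. KJCXn4 against KJC335 on xylose has the shortest bars, with 703 genes higher and 670 lower.

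KJC19-9 against KJC335, both on xylose, compared the strain evolved on this sugar with its parent. CLO1313_RS09935 was at 1649 ± 100.04 CPM in KJC19-9 and at 6.11 ± 0.337 CPM in the parent, and CLO1313_RS09930 at 1031 ± 76.7 and 32.6 ± 2.39 CPM (SD, n = 3 each). Their log2 fold changes were 8.08 and 4.98 (edgeR adjusted p = 8.03e-11 and 1.16e-09). CLO1313_RS14785 fell to 7.12 ± 0.797 CPM and CLO1313_RS14790 to 8.98 ± 0.592 CPM (SD, n = 3 each), with log2 fold changes of -5.67 and -5.44 (edgeR adjusted p = 2.02e-12 and 2.33e-13). These are the same 4 tags, moved in the opposite direction, as in the sugar comparison of the parent, and both comparisons use the same parent xylose libraries.

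In this comparison 2153 genes were called, 1057 higher and 1096 lower in KJC19-9, and 517 changed at least 2-fold, 234 higher and 283 lower. The 2-fold changes formed 25 runs with 200 rows, the longest of 27 rows, against at most 6 rows in shuffled order. Of the 252 genes at least 2-fold higher on xylose in KJC335, 141 were at least 2-fold lower in KJC19-9 than in KJC335 on xylose, and of the 168 at least 2-fold lower, 86 were at least 2-fold higher. Independent lists would share 23.7 and 13.1 such genes. The covariance of the log2 fold changes in these comparisons was -0.529 against a median of -0.0107 in 50 simulations of unchanged groups around the same parent xylose libraries. Pearson's r was -0.695 against a simulated median of -0.501, so groups without change already correlate negatively. The simulated covariance is about what independent noise of the shared parent libraries adds, whether or not the other groups change. A deviation common to all parent xylose libraries was not simulated. The parent xylose libraries enter both comparisons, so part of the opposition may come from them. The sugar comparison of KJC335 shares no library with KJCXn4 over KJC19-9 on xylose, and these correlated with r = 0.497 and rho = 0.434. At least 2-fold changes went in the same direction for 133 genes and in opposite directions for 18. Independent lists would give 27.2 and 27.1. Genes higher on xylose in KJC335 thus tended to be lower in KJC19-9 than in KJCXn4. That does not measure the part the parent libraries add. Set against KJC335 on cellobiose, the same 252 genes had a median log2 fold change of 0.31 in KJC19-9 on xylose and of 1.53 in KJC335 on xylose. The 168 lower genes had medians of -0.57 and -1.35. The genes were selected on the parent libraries, and the same cellobiose libraries are the baseline of both medians, so these medians are not independent.

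KJCXn4 against KJC335, both on xylose, asked the same of the strain evolved on xylose plus xylan. CLO1313_RS11350 rose from 136.1 ± 2.28 to 1504 ± 250.9 CPM (SD, n = 3 each), a log2 fold change of 3.47 (edgeR adjusted p = 8.44e-12). CLO1313_RS14785 fell to 16.5 ± 1.88 CPM and CLO1313_RS14790 to 21.4 ± 2.73 CPM (SD, n = 3 each), with log2 fold changes of -4.46 and -4.19. The next largest rise was that of CLO1313_RS02235, with a log2 fold change of 1.94 and a standard error of 0.51. It is 1 of 7 among the 8 largest rises whose counts are nearly those of other rows in every library, so these values are uncertain.

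Here 1373 genes were called, 703 higher and 670 lower in KJCXn4, and 122 changed at least 2-fold, 26 higher and 96 lower. The run of 8 rows ending in CLO1313_RS14790 was lower, with a median log2 fold change of -3.05. The 252 genes at least 2-fold higher on xylose in the parent had a median log2 fold change of 0.78 in KJCXn4 on xylose against KJC335 on cellobiose, and the 168 lower genes one of -1.14. Against KJC335 on xylose, 76 of the 252 were at least 2-fold lower in KJCXn4 and 6 of the 168 at least 2-fold higher, where independent lists would share 8.05 and 1.45. Over all called genes, without the 2-fold threshold, 430 of 963 and 458 of 981 were called in the opposite direction, 44.7% and 46.7%, where independent lists would share 214.7 and 229.5. The parent xylose libraries enter these counts on both sides as well.

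The evolved strains shared 453 genes called higher and 438 called lower than the parent on xylose. Independent lists of the same sizes would share 247.3 and 244.4. In 50 simulations of unchanged groups, with the shared parent libraries also drawn anew around their mean, the shared calls numbered 0 at the highest. That follows from groups that hold no changed gene and is no measure of what the parent libraries add among genes that do change. The log2 fold changes correlated across genes with Pearson's r = 0.574 and Spearman's rho = 0.435. The simulations gave a median r of 0.492 and a median rho of 0.460. They left out the pairing of same-numbered libraries of the evolved strains, a further link between these comparisons. The covariance was 0.271 against a simulated 0.0104, a difference of 0.261. The parent libraries were too few to split, so part of the excess in shared calls may come from them. At a 2-fold threshold in both, 11 genes were higher and 79 lower, where independent lists would share 2.02 and 9.04. Of the 11 rises, 8 lay in sets of near-identical rows, and 3 were left without these rows, where independent lists would share 1.44. The rises also numbered 3 without KJC19-9 xylose replicate 3 and 3 without KJC335 xylose replicate 2.

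Xylan was added to xylose in cultures of KJCXn4. CLO1313_RS09935 rose from 5.67 ± 1.73 CPM on xylose to 2558 ± 53.2 CPM with xylan, and CLO1313_RS09930 from 18.5 ± 0.860 to 1333 ± 22.8 CPM (SD, n = 3 each). The log2 fold changes were 8.80 and 6.17 (edgeR adjusted p = 1.21e-10 and 3.97e-10). CLO1313_RS04395 fell from 4042 ± 394.3 to 256.6 ± 28.3 CPM and CLO1313_RS13955 from 5323 ± 1561 to 464.2 ± 9.54 CPM (SD, n = 3 each), with log2 fold changes of -3.98 and -3.52.

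With xylan 1996 genes were called, 994 higher and 1002 lower, and 402 changed at least 2-fold, 189 higher and 213 lower. Scaling by library totals alone gave 655 higher and 1410 lower, with 125 higher and 319 lower by at least 2-fold, and moved the median log2 fold change by -0.19. The 2-fold changes formed 10 runs with 80 rows, against at most 5 rows in shuffled order. Of these 10 runs, 8 had every row called in the same direction in KJC19-9 against KJC335, a comparison that shares no library with this one. Of all genes 71.6% were called there, in either direction, and rows of a run are not independent. Read the other way, 13 of the 25 runs of KJC19-9 against KJC335 had every row called in the same direction with xylan. Across all 3005 genes the log2 fold changes of these comparisons correlated with Pearson's r = 0.564 and Spearman's rho = 0.458. At least 2-fold changes in the same direction were found for 181 genes and in opposite directions for 3, where independent lists would give 34.8 and 34.4. The response of KJC335 to xylose against cellobiose, which shares no library with the xylan comparison either, correlated with it at r = -0.421 and rho = -0.328.

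**Figure D3:**
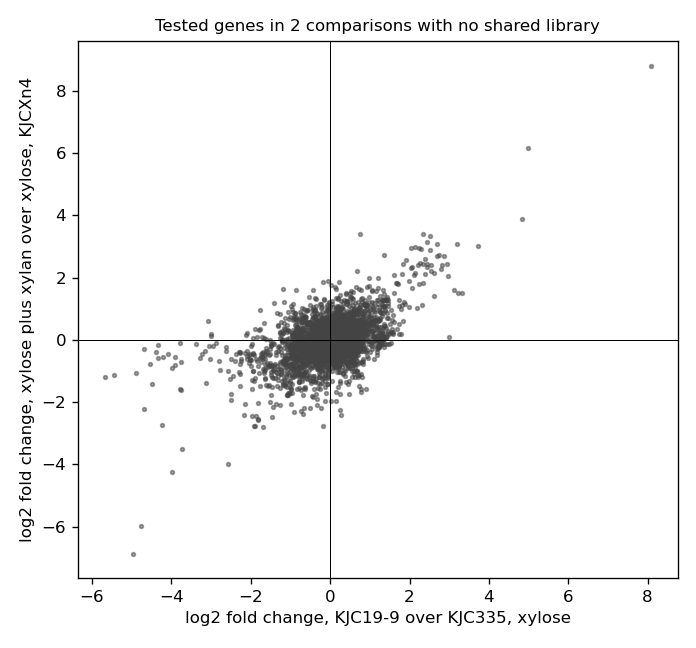
Log2 fold change of KJC19-9 over KJC335 on xylose (horizontal) and of xylose plus xylan over xylose in KJCXn4 (vertical); each point is 1 of the 3005 tested genes. The points rise together, with r = 0.564 across genes.

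The evolved strains were also compared directly on xylose. CLO1313_RS04395 was at 4042 ± 394.3 CPM in KJCXn4 and at 569.0 ± 17.9 CPM in KJC19-9, and CLO1313_RS10310 at 273.8 ± 32.7 and 52.3 ± 5.44 CPM (SD, n = 3 each). Their log2 fold changes, KJCXn4 over KJC19-9, were 2.83 and 2.39 (edgeR adjusted p = 1.45e-10 and 1.84e-09). CLO1313_RS09935 and CLO1313_RS09930 were lower in KJCXn4, with log2 fold changes of -8.17 and -5.80. XylB was higher in KJCXn4 by a log2 fold change of 0.36 (edgeR adjusted p = 0.0012). XylA had one of 0.16 and was not called (edgeR adjusted p = 0.062, between 0.020 and 0.238 over the alternatives). In all 2029 genes were called, 999 higher and 1030 lower in KJCXn4, and 389 changed at least 2-fold, 196 higher and 193 lower. The 2-fold changes formed 14 runs with 95 rows, against at most 5 rows in shuffled order.

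**Figure D4:**
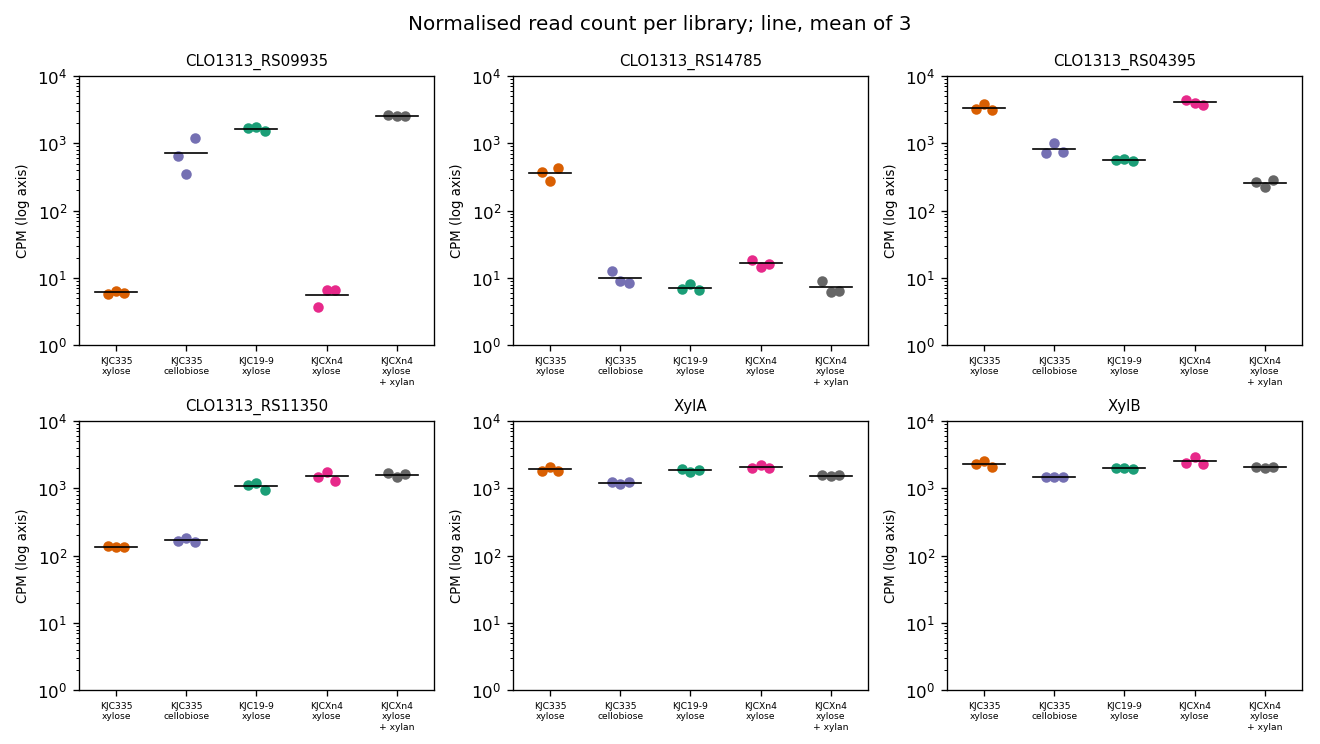
Normalised read count (CPM, log axis) of 4 locus tags and of XylA and XylB in each library; points are libraries, horizontal lines are means of 3 and colours are groups. CLO1313_RS09935 lies near 6 CPM in the xylose libraries of KJC335 and KJCXn4, and CLO1313_RS11350 is higher in the libraries of the evolved strains.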

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

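The test of exchanged labels had its bound and its verdict changed more than once after its value was seen. The tests of exchanged labels, of one regulatory state and of an earlier batch were chosen only after the results were seen. The test of other splits was set out before. The tests of near-identical rows and of the highest rows count separating genes, which were chosen after the data had been seen. They were thus not fixed before the data were examined, and the rules for separating genes and for near-identical rows took their last form later. Groups of 3 libraries were not tested for single outlying libraries.

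There were 226 genes called in opposite directions against KJC335 in KJC19-9 and KJCXn4. All of them were called between the strains as well, which opposite calls against 1 parent all but ensure. Independent lists of the same sizes would give 492.1 opposite calls, and at a 2-fold threshold in both strains there were 4, against 9.92. Such lists leave out the shared parent libraries, which push calls towards 1 direction, so neither number is a value without effect. CLO1313_RS09935 and CLO1313_RS09930 were set apart by the direct contrast, with log2 fold changes of -8.17 and -5.80, KJCXn4 over KJC19-9. CLO1313_RS14785 and CLO1313_RS14790 fell in both strains and by less in KJCXn4, with log2 fold changes of 1.21 and 1.25 between the strains. CLO1313_RS11350 rose in both, with 0.47 between them.

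KJC19-9 on xylose resembled KJCXn4 on xylose plus xylan. Their group means correlated with r = 0.985 across genes, against 0.972 for the xylose groups of both evolved strains and 0.971 for both groups of KJCXn4. KJC335 and KJCXn4 on xylose had a higher value, 0.986. The resemblance was partial, since 1820 of 3005 genes were called between KJCXn4 on xylose plus xylan and KJC19-9 on xylose, 236 of them at least 2-fold (edgeR). There were 33 genes that separated the 6 libraries of KJC19-9 on xylose and KJCXn4 on xylose plus xylan from the other 9. Of the 33, 29 were left when the 10 highest rows were taken out of the totals. That does not decide on a few genes taking most of the counts. The 10 highest rows took between 19.3% and 25.5% of every library, so the step rescales the libraries by similar factors. Genes picked for a gap of at least 1 on the log2 scale would mostly be left either way. An exchange of the labels of the KJC19-9 and KJCXn4 xylose libraries stays open and was not decided: 0 genes separated both KJCXn4 groups from the other 9 libraries, and the same held for 3 of the other pairs of groups. At a gap of 0.5 on the log2 scale both KJCXn4 groups had 2 such genes, the fewest of the 10 pairs of groups, next to 4 for the xylose groups of KJC335 and KJC19-9, so the outcome depends on the gap. One regulatory state reached in KJC19-9 by evolution and in KJCXn4 by xylan is a hypothesis that also stays open, with r = 0.564 between fold changes that share no library, and an exchange of labels could give that value too.

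All 9 libraries of the evolved strains stood apart from all 6 of the parent at 4 genes, or at 12 by group means alone. The 3 with a gap of at least 4-fold, named after their values were seen, were CLO1313_RS11350, higher in the evolved strains, and the adjacent CLO1313_RS04635 and CLO1313_RS04640, lower. On xylose, their log2 fold changes against the parent were 3.00, -3.01 and -3.01 in KJC19-9 and 3.47, -3.11 and -3.05 in KJCXn4. Of the 4 genes, 0 lie in sets of near-identical rows, and 3 were left without the 10 highest rows. Neither value decides on shared reads or on a few genes taking most of the counts. The sets hold 19 of the 3105 rows, so few genes of any kind lie in them. Taking out the highest rows only rescales each library, which could hardly close the gaps by which the genes were picked. An earlier batch of the parent libraries cannot be told apart from the strains at these 4 genes, because every parent library would be in it. Change by evolution stays open, untested.

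In each comparison the 6 libraries make 10 splits into 3 and 3, of which only 1, the real one, reached the real count; 10 splits are too few for a share under 0.05. Fitted to those 6 libraries by edgeR, the real split called 1878 genes for the sugars in KJC335, 2068 for KJC19-9 and 1373 for KJCXn4 against the parent, 2066 for xylan and 1931 between the evolved strains. The highest other split called 0 in each at the adjusted threshold, and at an unadjusted p under 0.05 at most 34, 29, 93, 20 and 31 genes in that order. Every other split mixes both groups on each side, which widens the spread of genes that differ between them. Low counts in the other splits thus follow from the design and give no level without effect. Between the evolved strains, whose replicate numbers pair, the 4 splits that part every pair include the real one, and the highest of the others called 0 genes, with 17 at the unadjusted threshold.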

How the results depend on the processing

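Leaving out the near-identical rows, and all settings of the overlaps but the 2-fold threshold and library totals, were chosen after seeing the data. The counts of called genes, of 2-fold changes and of the overlaps stayed within 1.5 times their value in 174 of 175 recomputations. The exception was the overlap at a 2-fold threshold in both strains, at 90 genes instead of 891, since that threshold takes fewer genes. With 1 library left out in turn the overlap ranged from 746 to 886. Of 419 recomputations for the named genes, 0 changed sign and 412 stayed on their side of the threshold. The others were XylB in KJC19-9 against the parent, lost in 3, and XylA between the evolved strains, called in 4, with log2 fold changes of 0.19 by library totals, 0.17 by DESeq2, 0.18 without a filter and 0.19 without KJC19-9 xylose replicate 1. Library totals moved the split of calls by more than 10 points for the sugars in KJC335 and for xylan in KJCXn4. A replicate block gave 1943 calls for the sugars in KJC335, 2178 for KJC19-9 and 1399 for KJCXn4 against the parent, 2008 for xylan and 2028 between the evolved strains, and changed no call of a named gene. The block fits the replicate number as 1 effect common to the groups. It is thus no paired test of the evolved strains alone. Where the numbers did not pair the libraries, each library still correlated best with its own number for KJCXn4 against the parent on xylose, and not in the other comparisons. The gene list alternatives and the one that keeps rRNA and tRNA rows were not run. No alternative varied the depth.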

Other observations

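These values were examined only after the results were seen. The genes that separated sets of groups were counted at a gap of 1 on the log2 scale. KJC335 on xylose stood apart from the other 12 libraries at 44 genes, higher at 44 and lower at 0. KJC335 on cellobiose stood apart at 36 genes, higher at 8 and lower at 28. The xylose libraries of KJC335 and KJCXn4 together stood apart from the other 9 at 43 genes, of which 9 were higher and 34 lower. Among the 9 were CLO1313_RS02705 and CLO1313_RS02710, which open the stretch of 5 rows with rises up to 7.61 in KJC335. KJC19-9 on xylose stood apart at 7 genes and so did KJCXn4 on xylose, while KJCXn4 on xylose plus xylan stood apart at 19, of which 8 lie in sets of near-identical rows. The order of the groups depends on the gap. At a gap of 0.5 the counts were 161 for KJC19-9 on xylose, 145 for KJCXn4 on xylose plus xylan, 134 for KJC335 on xylose, 133 for KJC335 on cellobiose and 47 for KJCXn4 on xylose.

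The ratio of XylA to XylB was 0.830 ± 0.025 in KJC335 on xylose, 0.815 ± 0.032 on cellobiose, 0.933 ± 0.060 in KJC19-9 on xylose, 0.817 ± 0.052 in KJCXn4 on xylose and 0.752 ± 0.0090 with xylan (SD, n = 3 each). These ratios are not corrected for gene length and were not tested against each other.

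Some rows had nearly the same counts in every library. The version of the rule used found 19 rows in 3 sets of 4 to 11 rows, which took between 0.175% and 2.37% of a library's counts. The first version tried, with a tolerance of 0.1, found 15 rows in 4 sets, and the second, with a tolerance of 0.2 and no bound on variation, found 75 rows in 17 sets. The median spread of such rows within groups lay at the 76.2nd percentile of other rows at least as abundant with the version used, at the 76.3rd with the first and at the 34.4th with the second, so it depends on the rule. No explanation was weighed, because the rows were picked by their constant ratio.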
